A study of Homo sapiens with 4 samples.

How the data were processed

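Gene expression was measured by RNA sequencing in 4 libraries of IMR90 fibroblasts: 2 of untreated normal cells and 2 of cells made senescent with bleomycin. Groups and replicate numbers were taken from the sample titles and treatment labels. Per the labels' protocols, cells grew at 3% oxygen in medium with 15% serum and 0.1 mM nonessential amino acids, RNA was extracted with acidic phenol, and 1 µg of RNA with an integrity number over 7 went into stranded poly(A) libraries (TruSeq Stranded mRNA) sequenced on an Illumina NovaSeq instrument.

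The values analysed are raw gene counts as deposited by the authors, whole numbers per NCBI gene ID with no normalization. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.1.0 and featureCounts 1.6.3 were used with the hg38 build. The gene annotation, the strand setting, the treatment of reads that align to several places or overlap several genes, and the read length are not given in the sources used here. Such choices can lower the counts of genes with near-identical copies, or assign reads of a gene to an antisense or overlapping neighbour. The count table has 28395 genes, of which 27745 were matched by gene ID to a symbol, a type and coordinates in the RefSeq annotation of GRCh38.p14, whose chromosomes are those of hg38, and 650 were not. Unmatched IDs hold 0.0586% to 0.0628% of the counts of a library, and 140 of them were tested.

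Totals ranged from 28929073 to 35294524 counts. At these depths a count of 0 allows up to 3 counts, or 0.0870 to 0.105 CPM in a library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The 10 most abundant genes took 8.09% and 7.94% of counts in the normal libraries and 11.0% and 10.9% in the senescent ones. TMM factors were 1.08 and 1.09 for normal and 0.917 and 0.930 for senescent libraries. Replicates were compared before averaging: the chi-square of their counts over its degrees of freedom was 3.03 for the normal and 4.81 for the senescent pair, so no library repeats another.

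Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 14367 (7726 had 0 counts in every library), scaled by TMM and fitted with the robust quasi-likelihood model with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM are counts divided by the TMM-scaled library total, on the usual edgeR scale. The SE of a log2 fold change was derived from its F statistic. The biological coefficient of variation was 0.0420. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

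Before the data were examined, 27 gene lists were fixed: pathways of senescence, DNA damage, secretion, chromatin, matrix, RNA processing, metabolism and stress, and markers of endothelial, epithelial and leukocyte cells. Each list was tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the 27 lists. The test was repeated with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and compares it with no other genes. Named genes followed a rule fixed at the same time. It took the 8 highest and 8 lowest log2 fold changes among protein-coding genes with adjusted p under 0.05, mean log2 CPM of at least 3 and no overlap between groups. It added, per list, up to 2 members that rose most and 2 that fell most with mean log2 CPM of at least 1 (or the most abundant member where none passed), and a fixed set of senescence genes. A few genes that the rule takes are not reported here. Other genes are named only where the text says that they were chosen after their values were seen, where they explain a missing or misplaced list member, or as counts that limit a list.

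Alternatives to the main settings were RLE and upper quartile factors, library totals alone, no low-count filter, a stricter filter (50 counts in 2 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, a test against a fold of 2, an adjusted p under 0.01, and leaving out each library in turn. The procedure was tested on simulated counts for the senescent against normal comparison with 14367 genes, 200 of them changed. It recovered 83 of 100 genes changed by 1.5-fold and 94 of 100 changed by 2-fold in the right direction, and called 13 unchanged genes. The changed genes were drawn from those with a mean over 1 CPM, so recovery below that level was not tested. Simulated rises and falls were equal in number, and gene dispersions came from these same libraries. In the data 73.6% of tested genes were called. The simulation therefore shows nothing about scaling under such broad change or about variation between cultures. Antisense pairs were compared where the antisense gene had a mean log2 CPM of at least 1, and again with no such minimum. Exon overlaps and shared 75-base words of transcripts were computed from GENCODE 29 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.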

Results

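Messenger RNA was sequenced from IMR90 cells, an established line of human fetal lung fibroblasts, in 2 states. The line is known for a finite replicative life span, which was not examined in these cultures. Normal cells were untreated (n = 2 libraries). Senescent cells had been exposed to 10 µg/ml bleomycin, an agent that breaks DNA, for 24 h and were collected 10 days after the exposure (n = 2 libraries). Cultures were kept at 3% oxygen. The deposited gene counts summed to 31928364 and 28929073 in normal replicates 1 and 2, and to 35294524 and 30727879 in senescent replicates 1 and 2. Between 17513 and 18665 genes had at least 1 count in a library. Across tested genes, log2 CPM (counts scaled to the library size after TMM correction) had a Pearson r of 0.995 between the normal replicates and of 0.994 between the senescent replicates, against 0.924 to 0.929 between libraries of different groups. The single comparison asked how messenger RNA levels differ between senescent and normal cells. Values per gene are mean CPM ± SD (n = 2 per group), and log2 fold changes (senescent over normal) are given ± SE.

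Bleomycin-exposed cells carried far more RNA of secreted inflammatory factors and of interferon-stimulated genes than untreated cells, and far less RNA of genes for DNA replication and mitosis. The tests of these lists did not pass with a correlation estimated from the data, a setting in which the 2 residual degrees of freedom limit the test. Of 14367 genes tested, 5191 were higher and 5381 lower in senescent cells, and 3795 were not called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Many of these changes were small, and 4616 of the called genes changed by less than 1.5-fold. 1849 genes were higher and 1390 lower by 2-fold or more, and 249 were higher and 131 lower by 8-fold or more. Scaling by library totals alone lowered the median log2 fold change by 0.23 (a shift of -0.23) and gave 3705 higher and 7241 lower genes, 33.8% of calls higher against 49.1%. Of the 3239 calls of 2-fold or more, 3193 were still called in the same direction with that scaling and 0 were reversed. The direction of small changes is therefore relative to the scaling used.

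**Figure D1:**
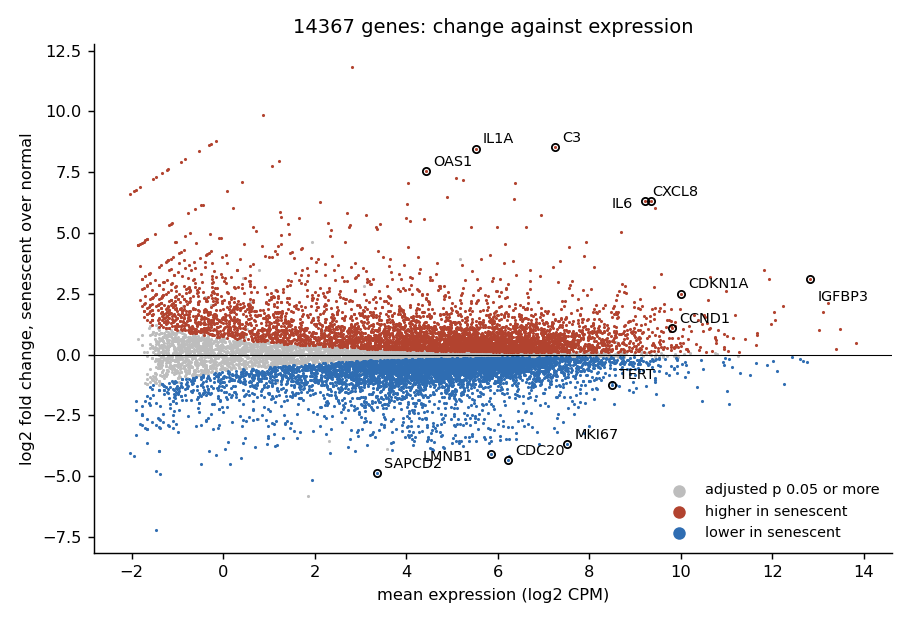
Log2 fold change (senescent over normal, vertical axis) against mean expression (log2 CPM, horizontal axis) for the 14367 tested genes, 1 point per gene, coloured by the edgeR call. IGFBP3 and CDKN1A combine a high level with a rise (3.11 and 2.50), whereas MKI67 and CDC20 lie far below 0 (-3.68 and -4.35). Points in diagonal lines at the left are genes with 0 or few counts in a group, whose fitted values depend on the prior count.

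Among protein-coding genes with a mean log2 CPM of at least 3, the 8 with the highest fold changes were immune and secreted factors together with an epithelial transcription factor. C3 (gene ID 718, GRCh38 chromosome 19, 6677704 to 6720650), the central complement component, went from 0.809 ± 0.333 to 303 ± 0.157 CPM (log2 fold change 8.52 ± 0.0980, adjusted p = 4.29e-25). IL1A (3552, chromosome 2, 112773925 to 112784493), the cytokine interleukin-1 alpha, went from 0.251 ± 0.219 to 92.1 ± 7.63 CPM (8.46 ± 0.171), and its estimate rested on 14 and 3 counts in the normal libraries, with values of 9.86 and 7.81 when normal replicate 1 or normal replicate 2 was left out. The antiviral genes OAS1, BST2 and OAS2 rose by 7.55, 7.20 and 6.47, the cytokine genes CSF2 and CXCL10 by 7.25 and 7.07, and the transcription factor gene EHF by 7.06, all on the log2 scale. The OAS2 estimate was 5.74 without normal replicate 1 and 7.81 without normal replicate 2. At the other end stood SAPCD2 (-4.87), the anaphase activator CDC20 (-4.35), the mitotic kinesin KIF20A (-4.16), the lamin gene LMNB1 (-4.07), PIMREG (-3.94), the centromeric histone CENPA (-3.90), the condensin subunit NCAPH (-3.87) and TROAP (-3.86). CDC20 (991, chromosome 1, 43358981 to 43363203) fell from 141 ± 2.84 to 6.93 ± 0.886 CPM (adjusted p = 1.52e-22).

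RNA of 3 cyclin-dependent kinase inhibitor genes of the fixed set rose. CDKN1A (1026, chromosome 6, 36676463 to 36687332), which encodes p21, went from 307 ± 11.9 to 1745 ± 114 CPM, a 5.68-fold rise (log2 fold change 2.50 ± 0.0497, adjusted p = 2.37e-21). CDKN2A (1029, chromosome 9, 21967752 to 21995324), whose single count covers both p16INK4a and p14ARF, rose from 10.8 ± 0.184 to 20.7 ± 0.299 CPM (0.93 ± 0.0836), and CDKN2B, which encodes p15, from 3.60 ± 0.540 to 10.1 ± 0.258 CPM (1.49 ± 0.131). RNA of RB1, the retinoblastoma gene, was lower, at 73.2 ± 5.26 in normal and 50.1 ± 0.321 CPM in senescent cells (-0.55 ± 0.0574). CCND1, which encodes cyclin D1, rose by 1.08, while the transcription factor gene E2F1 fell by 1.99 on the log2 scale. Of 30 p53 target genes, 24 rose, 2 fell and 4 were not called (median log2 fold change 0.75, camera adjusted p = 7.64e-10, and adjusted p = 0.142 with an estimated correlation). The largest rises were those of the stress cytokine GDF15 (3.76, from 9.63 ± 1.55 to 131 ± 3.53 CPM) and the antiproliferative gene BTG2 (2.82), and the ubiquitin ligase gene MDM2 rose by 0.70. TP53I3 (-0.64) and AEN (-0.21) were the members that fell. With library totals 5 members fell in place of 2. The call of AEN was lost with DESeq2 (adjusted p = 0.0565) and without normal replicate 1, normal replicate 2 or senescent replicate 1 (adjusted p = 0.0994, 0.0728 and 0.250).

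Genes of cell division fell almost without exception. All 38 DNA replication genes fell (median -2.45, camera adjusted p = 4.33e-44, and adjusted p = 0.154 with an estimated correlation), among them the replication initiation genes MCM10 (-3.65) and ORC1 (-3.28). All 47 mitosis genes fell, 46 of them by 2-fold or more (median -3.25, camera adjusted p = 1.36e-98, and adjusted p = 0.142 with an estimated correlation). MKI67 (4288, chromosome 10, 128096659 to 128126423), the gene of the proliferation marker Ki-67, went from 337 ± 13.1 to 26.4 ± 4.86 CPM (-3.68 ± 0.103, adjusted p = 1.46e-08). In the list for homologous recombination and the Fanconi pathway, which repairs DNA crosslinks, 30 of 31 genes fell and 1 was not called (median -1.75, camera adjusted p = 1.91e-12, and adjusted p = 0.154 with an estimated correlation), with XRCC2 (-3.15) and the helicase gene BLM (-3.06) lowest.

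In the list for nuclear lamina and chromatin architecture, 30 of 34 members fell, 2 rose and 2 were not called (median -1.97, camera adjusted p = 5.35e-33, and adjusted p = 0.142 with an estimated correlation). LMNB1 (4001, chromosome 5, 126776623 to 126837020), which encodes lamin B1, went from 109 ± 1.10 to 6.51 ± 0.988 CPM, 16.8-fold lower (-4.07 ± 0.0767, adjusted p = 1.08e-21). The DNA-bending proteins' genes HMGB1 and HMGB2 fell from 381 ± 16.2 to 96.2 ± 1.69 and from 159 ± 0.425 to 24.6 ± 0.542 CPM (-1.99 ± 0.0484 and -2.69 ± 0.0540). The members that rose, LEMD2 (0.65) and SUN1 (0.38), encode proteins of the inner nuclear membrane. Canonical histone genes, whose messages mostly lack a poly(A) tail and are thus poorly captured in such libraries, were tested for 13 of 59 members. Of these 8 rose, 2 fell and 3 were not called (median 1.68, camera adjusted p = 0.0289, and adjusted p = 0.397 with an estimated correlation), with H2BC5 (2.66) and H2BC12 (2.25) highest. Falling members numbered 7 with no low-count filter, which adds members with few counts, 0 with the stricter filter and 1 without normal replicate 2. The call of this list was lost without the low-count filter (adjusted p = 0.790), with DESeq2 (0.0612) and without senescent replicate 2 (0.0727), within a range of 0.00129 to 0.790 over all alternatives.

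**Figure D2:**
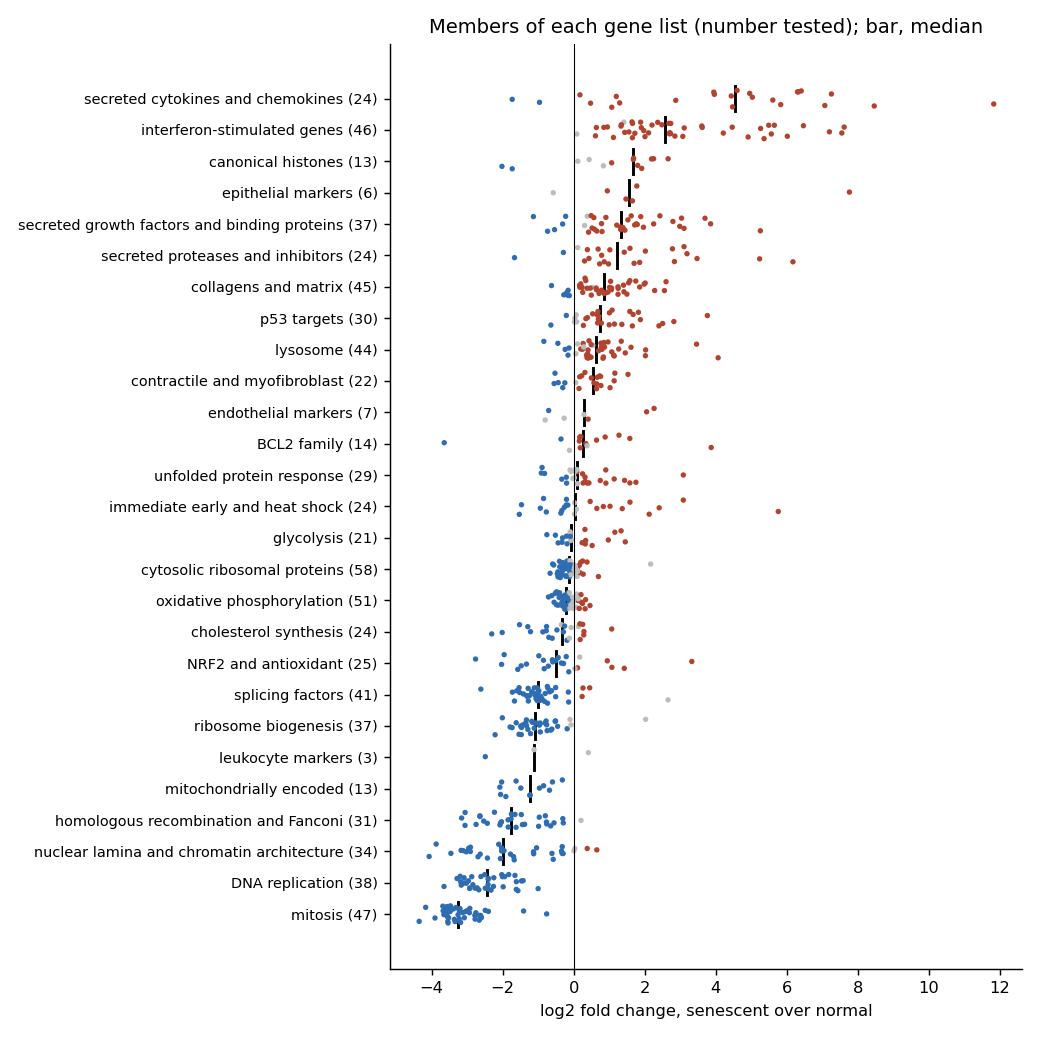
Log2 fold change (senescent over normal) of each tested member of the 27 gene lists, 1 point per gene, in red where it rose, in blue where it fell and in grey where it was not called. Black bars mark list medians, from -3.25 for mitosis to 4.54 for secreted cytokines and chemokines, and the number tested stands beside each name. The point at the far right is CCL20, which had 0 counts in normal cells. With library totals the fitted direction of the glycolysis list changed from up to down.

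Secreted inflammatory factors rose together. Of 36 cytokine and chemokine genes, 24 had enough counts to be tested, of which 22 rose, 20 of them by 2-fold or more, and 2 fell (median 4.54, camera adjusted p = 8.99e-39, and adjusted p = 0.115 with an estimated correlation). IL6 (3569, chromosome 7, 22727200 to 22731998) went from 16.1 ± 1.12 to 1291 ± 62.2 CPM, a 79.8-fold rise (6.32 ± 0.0624, adjusted p = 4.95e-26), and CXCL8 (3576, chromosome 4, 73740569 to 73743716), the neutrophil chemokine interleukin-8, from 14.8 ± 0.645 to 1169 ± 112 CPM (6.30 ± 0.0740). IL1B, the partner of IL1A in interleukin-1 signalling, reached 162 ± 4.02 CPM from 1.91 ± 0.131 (6.40 ± 0.0810), and the monocyte chemokine gene CCL2 reached 32.0 ± 3.33 from 1.47 ± 0.0524 (4.44 ± 0.122). The chemokine gene CCL20 had 0 counts in normal cells and 14.3 CPM in senescent cells, at least 313-fold higher against a floor of 3 counts over the normal group. CXCL12 (-1.73) and TNFRSF11B (-0.96), which encodes the decoy receptor osteoprotegerin, fell.

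Of 24 tested genes for secreted proteases and their inhibitors, 21 rose, 2 fell and 1 was not called (median 1.22, camera adjusted p = 6.56e-19, and adjusted p = 0.154 with an estimated correlation). The stromelysin gene MMP3 (4314, chromosome 11, 102835801 to 102843609) rose from 0.532 ± 0.0139 to 20.1 ± 0.927 CPM (5.23 ± 0.151, adjusted p = 1.71e-18) and the collagenase gene MMP1 from 166 ± 1.99 to 673 ± 37.1 CPM (2.02 ± 0.0477), while MMP16 (-1.66) and ADAMTS1 (-0.29) fell. Among 37 genes for growth factors and their binding proteins, 30 rose, 5 fell and 2 were not called (median 1.32, camera adjusted p = 3.82e-22, and adjusted p = 0.154 with an estimated correlation). BMP2 (5.25) and ANGPTL4 (3.85) rose most, and KITLG (-1.13) and IGF2 (-0.73) fell most. The number of falling members was 3 in place of 5 without normal replicate 1, normal replicate 2 or senescent replicate 2, and with DESeq2. The insulin-like growth factor binding proteins' genes IGFBP3 and IGFBP5, already abundant in normal cells at 1511 ± 57.2 and 3999.8 ± 211 CPM, reached 12999 ± 753 and 13559 ± 208 CPM (3.11 ± 0.0480 and 1.76 ± 0.0434). The risers of this list include PIGF (0.65), which acts in the synthesis of GPI anchors and is not a growth factor.

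Interferon-stimulated genes showed 44 rises, 40 of them of 2-fold or more, among 46 tested members, with 0 falls and 2 genes not called (median 2.58, camera adjusted p = 1.08e-42, and adjusted p = 0.154 with an estimated correlation). OAS1 (4938, chromosome 12, 112906962 to 112933219), which makes the activator of RNase L, went from 0.230 ± 0.0797 to 43.4 ± 6.12 CPM (7.55 ± 0.181, adjusted p = 9.70e-18), and BST2, which encodes the virus-retaining protein tetherin, from 0.520 ± 0.120 to 76.4 ± 5.13 CPM (7.20 ± 0.125). The class I antigen presentation members TAP1, PSMB8 and PSMB9 had 2, 0 and 4 counts over all 4 libraries and were not tested, while HLA-B had 32457. In this part of chromosome 6, between GABBR1 and KIFC1, 95.1% of 143 protein-coding genes lay under 1 CPM, against 38.7% of such genes outside this and a pair of similar stretches on chromosomes 17 and 19. The bounds of these stretches were chosen after the values were seen, so the contrast only describes the data. The low counts of TAP1, PSMB8 and PSMB9 are not read here as lack of expression.

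**Figure D3:**
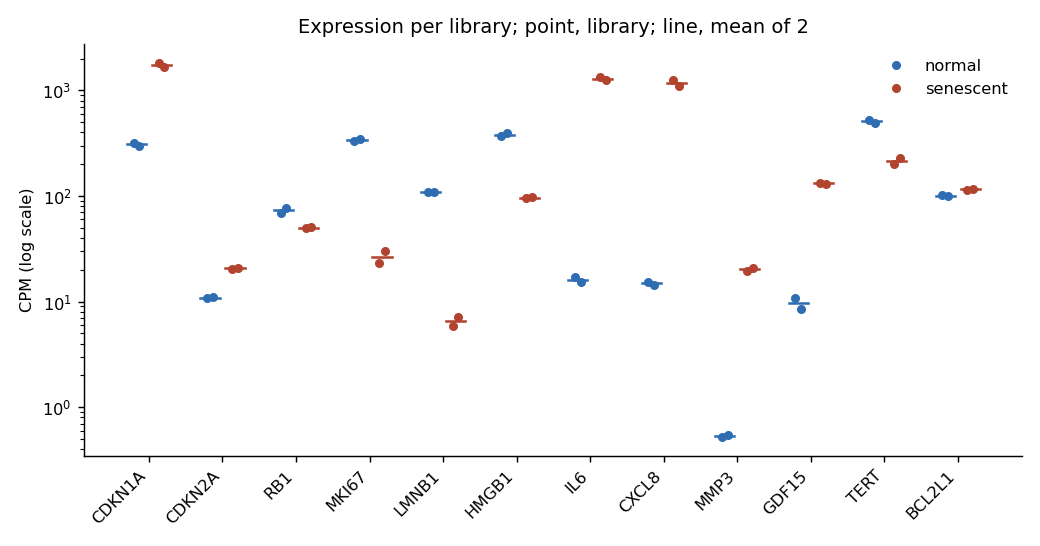
CPM on a log scale for 12 genes of the fixed set, 1 point per library and a line at the mean of the 2 libraries of each group. The libraries of a group lie close together beside the gap between groups for CDKN1A, LMNB1, IL6 and CXCL8, and the gap is smallest for BCL2L1 (0.20 on the log2 scale), whose direction changed with library totals (-0.027).

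Extracellular matrix and contractile genes rose more often than they fell. Of 45 collagen and matrix genes, 38 rose, 6 fell and 1 was not called (median 0.85, camera adjusted p = 1.01e-15, and adjusted p = 0.225 with an estimated correlation). The collagen-crosslinking enzyme genes LOX and LOXL4 led the list (2.60 and 2.55), with LOX rising from 577 ± 8.59 to 3502 ± 189 CPM, whereas PCOLCE (-0.62) and COL18A1 (-0.28) fell most. Without normal replicate 1, 3 members fell in place of 6. In the contractile and myofibroblast list 16 of 22 tested genes rose, 5 fell and 1 was not called (median 0.53, camera adjusted p = 0.00363, and adjusted p = 0.359 with an estimated correlation). ITGA11 (1.53) and CNN1 (1.16) rose most, and S100A4 (-0.55) and TGFB1I1 (-0.52) fell most.

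Among 44 tested lysosomal genes, 34 rose, 5 fell and 5 were not called, or 36, 5 and 3 when adjusted over the list alone (median 0.62, camera adjusted p = 2.39e-09, and adjusted p = 0.227 with an estimated correlation). GLB1 (2720, chromosome 3, 32961108 to 33097146), which encodes the lysosomal beta-galactosidase, went from 80.3 ± 2.73 to 137 ± 2.08 CPM (0.77 ± 0.0487, adjusted p = 2.73e-12). The protease gene CTSS (4.07) and the fucosidase gene FUCA1 (3.46) rose most, and PPT1 (-0.84) and ATP6V0D1 (-0.44) fell most. Falling members numbered 2 without normal replicate 1, and 3 with DESeq2 or the stricter filter. NEU1, on chromosome 6, had 0 counts in every library.

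All 13 protein-coding genes of the mitochondrial genome fell (median -1.24, camera adjusted p = 1.67e-13, and adjusted p = 0.227 with an estimated correlation), with ATP8 and CYTB lowest (-2.08 and -2.06). Counts of genes on the mitochondrial chromosome made up 3.25% and 3.27% of the normal libraries and 1.30% and 1.42% of the senescent ones. Nuclear genes of oxidative phosphorylation changed little: 32 of 51 fell, 8 rose and 11 were not called, or 34 fell and 8 rose when adjusted over the list alone (median -0.21, camera adjusted p = 0.0908). NDUFA9 (-0.61) and ATP5MC1 (-0.71) fell most and NDUFA1 (0.46) and NDUFB5 (0.34) rose most. Cytosolic ribosomal protein genes had 37 falls and 8 rises among 58 tested, or 38 and 9 when adjusted over the list alone (median -0.14, camera adjusted p = 0.0595). Among called genes RPSA (-0.66) and RPS2 (-0.59) fell most, and RPS19 (0.70) and RPL28 (0.38) rose most. With library totals the oxidative phosphorylation and ribosomal protein lists passed the threshold as lower (adjusted p = 0.0148 and 0.000695), with 1 and 2 rising members in place of 8 in each.

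Most genes of RNA processing fell. Of 37 ribosome biogenesis genes, 34 fell, 0 rose and 3 were not called (median -1.09, camera adjusted p = 6.85e-12, and adjusted p = 0.154 with an estimated correlation), with UTP20 (-2.21) and UTP14A (-2.01), components of the machinery that makes the small ribosomal subunit, lowest. Without senescent replicate 2 there was 1 rising member in place of 0. Of 41 tested splicing factor genes, 37 fell, 3 rose and 1 was not called (median -1.01, camera adjusted p = 3.42e-19, and adjusted p = 0.115 with an estimated correlation). HNRNPM (4670, chromosome 19, 8444975 to 8489114) went from 268 ± 1.81 to 44.0 ± 5.76 CPM (-2.61 ± 0.0651) and SRSF3 fell by 1.72 on the log2 scale, while SF3B1 (0.45) and SRSF11 (0.26, not called with library totals) rose. With library totals 1 splicing factor gene rose in place of 3. In these groups of usually abundant messages RPS18, PRPF8, RPS9, RRN3 and U2AF1 had 1, 4, 182, 98 and 268 counts over all 4 libraries, and their levels cannot be read from this table. Senescent replicate 1 held 215 of the U2AF1 and 75 of the RRN3 counts, and senescent replicate 2 held 134 of the RPS9 counts.

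Metabolic lists were mixed. Of 24 tested cholesterol synthesis genes, 14 fell, 6 rose and 4 were not called (median -0.32, camera adjusted p = 0.00477, and adjusted p = 0.269 with an estimated correlation). ACAT2 (-2.01) was among those that fell most, and TM7SF2 (1.07) and DHCR7 (0.29, not called with library totals) rose most. With library totals 1 member rose in place of 6. Glycolysis genes went both ways, with 9 rises, 8 falls and 4 not called among 21, or 9 rises and 10 falls when adjusted over the list alone (camera adjusted p = 0.515). Their median (-0.08) and mean (0.17) differed in sign, the test pointed up, and with library totals it pointed down (adjusted p = 0.873). The glucose transporter gene SLC2A3 (1.45) and PFKFB4 (1.33) rose most, and ENO1 (-0.75) and LDHA (-0.51) fell most. Among 25 genes of the NRF2 and antioxidant list 18 fell, 5 rose and 2 were not called (median -0.50, camera adjusted p = 0.00207, and adjusted p = 0.154 with an estimated correlation). NQO1 went from 300.0 ± 8.16 to 44.3 ± 0.954 CPM (-2.76 ± 0.0510), whereas SOD2, the mitochondrial superoxide dismutase gene, rose from 137 ± 4.43 to 1371 ± 121 CPM (3.32 ± 0.0569) and GPX3 rose by 1.42.

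Stress and survival genes also split. In the unfolded protein response list 15 of 29 genes rose, 6 fell and 8 were not called (median 0.11, camera adjusted p = 0.0289, and adjusted p = 0.227 with an estimated correlation), with ATF3 (3.09) and DNAJB9 (1.75) highest and SDF2L1 (-0.91) and PHGDH (-0.89) lowest. Library totals ended that call (adjusted p = 0.107) and raised the falling members from 6 to 15. Of 14 tested BCL2 family genes, which control apoptosis, 10 rose, 2 fell and 2 were not called (median 0.27, camera adjusted p = 0.0722). With library totals 6 members rose in place of 10, and with the stricter filter 1 fell in place of 2. Log2 fold changes in the list ran from -3.64 to 3.87, and 3 rises and 1 fall were of 2-fold or more. The members named here are limited to a mean log2 CPM of at least 1. The death-promoting genes BBC3 (1.58) and PMAIP1 (1.28) rose, the survival gene BCL2L1 rose from 101 ± 1.08 to 116 ± 1.18 CPM (0.20 ± 0.0472), a direction that library totals turned to -0.027, and BMF fell (-0.36). The call of BMF was lost with DESeq2 (adjusted p = 0.0720) and without normal replicate 1 (0.103). Immediate early and heat shock genes, which respond to handling as well as to treatment, had 10 rises, 11 falls and 3 not called among 24 (median 0.03, camera adjusted p = 0.509), with a rise of EGR2 (5.76) and falls of the chaperone genes HSPH1 (-1.47) and HSPA8 (-0.94). The heat shock genes HSPA1A and HSPA1B, in the chromosome 6 stretch given above, had 0 and 1 counts over all libraries. Their levels cannot be read here.

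TERT (7015, chromosome 5, 1253167 to 1295068), the catalytic subunit of telomerase, was counted at 507 ± 23.3 CPM in normal and 215 ± 22.0 CPM in senescent cells (-1.24 ± 0.0598, adjusted p = 2.23e-11). It ranked 222 of 14367 tested genes by mean CPM in normal cells. Most markers of other cell types were low, and none of their lists passed the test. Of 14 endothelial markers 7 were tested, of which 3 rose, 1 fell and 3 were not called (median 0.29, camera adjusted p = 0.109). TEK was the most abundant riser, from 35.1 ± 0.0283 to 146 ± 3.53 CPM, EGFL7 rose by 2.26 and ROBO4 fell (-0.70), while CDH5 had 0 counts in every library. With library totals 2 of these members fell in place of 1. Of 14 epithelial markers 6 were tested, with 5 rises, 0 falls and 1 not called (median 1.56, camera adjusted p = 0.171). Library totals gave 1 falling member in this list, the stricter filter left 3 rising members in place of 5, and MUC1 (1.78, 13.2 ± 1.29 CPM in senescent cells) was its most abundant member. ELF3 went from 1 count over the normal libraries to 254 over the senescent ones, a ratio of 275 (95% exact counting interval 48.9 to 10892). Its fitted log2 fold change was 10.00 without normal replicate 1 and 6.98 without normal replicate 2. Of 16 leukocyte markers 3 were tested, of which CORO1A fell (-2.49) and 2 were not called (median -1.11, camera adjusted p = 0.582). With library totals 2 members of this list fell, and with no low-count filter 1 rose.

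In all, 10 of the 27 lists rose and 9 fell. None of the 19 calls held with a correlation estimated from the data, a test that the 2 residual degrees of freedom limit. That includes p53 targets, whose estimated correlation of 0.0114 lay close to the preset of 0.01. The estimate lay far above the preset for mitochondrially encoded genes (0.801), interferon-stimulated genes (0.453), mitosis (0.377) and DNA replication (0.320), among others. Camera p-values of such lists depend on the preset. It lay below the preset for cytokines (-0.0243), splicing factors (-0.0153), NRF2 (-0.0114) and the unfolded protein response (0.00307). Fry, which sets no list against other genes, lost none of the 19 calls. With 73.6% of tested genes called, it also passed every other list but glycolysis (fry adjusted p = 0.0931), so it separates few lists. For the lists where no count adjusted over the list alone is given, the numbers of rising and falling members were the same with that adjustment. Because it is not known whether counting used strand, values of genes whose exons share over 20% of their bases with exons of a gene on the opposite strand are uncertain, which among the genes with a log2 fold change given above applies to IL6, BCL2L1, SAPCD2, ACAT2, NDUFA1, PPT1 and PIGF. The same holds for ATP8, IGF2 and RPS2, which share over 20% with a gene on the same strand.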

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

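Apart from the splits and counts given here, the 4 counts of changed genes stayed within 1.5 times their reported values, and all 116 named genes kept their direction and call under RLE factors, upper quartile factors, both filters, limma-voom and without senescent replicate 2. The count of genes lower by 2-fold or more was 2086 with library totals, and testing against a fold of 2 left 1199 higher and 879 lower genes. Library totals turned BCL2L1 to -0.027 and the glycolysis list to down (adjusted p = 0.873), ended the unfolded protein response call (0.107) and brought calls for oxidative phosphorylation (0.0148) and cytosolic ribosomal proteins (0.000695), all in the direction of its shift of -0.23. The calls of NDUFB5, SRSF11 and DHCR7 were lost with it (adjusted p = 0.224, 0.542 and 0.462). Without the low-count filter, which adds genes with few counts, the histone call was lost (0.790), the leukocyte list turned to up (0.910), and calls came for oxidative phosphorylation (0.000326), ribosomal proteins (0.000178), BCL2 family (0.0126) and epithelial markers (0.0400). The stricter filter brought a call for endothelial markers (0.0306). DESeq2 lost the histone call (0.0612) and brought one for ribosomal proteins (0.0308), and limma-voom brought calls for oxidative phosphorylation (0.00747), ribosomal proteins (0.00327) and BCL2 family (0.0228). Leaving out each library in turn gave adjusted p from 0.0160 to 0.0727 for histones, lost without senescent replicate 2, from 0.0415 to 0.147 for oxidative phosphorylation, called without senescent replicate 1, and from 0.0181 to 0.123 for ribosomal proteins, called without senescent replicate 1 or normal replicate 2. Except with library totals, the cause was not tested. With an estimated correlation all 19 list calls were lost: adjusted p was 0.115 for cytokines and splicing factors, 0.142 for p53 targets, mitosis and nuclear lamina and chromatin architecture, 0.154 for DNA replication, homologous recombination, proteases, growth factors, interferon-stimulated genes, ribosome biogenesis and NRF2, 0.225 for collagens, 0.227 for lysosome, mitochondrially encoded genes and the unfolded protein response, 0.269 for cholesterol synthesis, 0.359 for contractile genes and 0.397 for histones. Fry, which sets no list against other genes, lost none of the 19 calls. It brought calls for oxidative phosphorylation and immediate early genes (both 0.0287), ribosomal proteins (0.0450), BCL2 family (0.00413), endothelial (0.00282), epithelial (0.00191) and leukocyte markers (0.0229). A fit with the replicate number as a block (replicate block) called 5198 genes higher and 5372 lower and changed no list call, with 1 rising member of ribosome biogenesis in place of 0, and same-numbered libraries did not deviate together (correlation of deviations -0.0252), so equal numbers are not read as pairs. With 28929073 counts or more per library, counting error limits genes near the floor of 3 counts, such as most leukocyte markers and histones. Their low counts need not come from depth, since canonical histone messages mostly lack a poly(A) tail.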

Other observations

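The genes in the next 2 paragraphs, and the tests of cell type markers, an introduced sequence, overlapping against separate antisense pairs, joint regulation, alternate assembly sequences and loss of a chromosome stretch, were chosen after the values were seen.

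Some genes linked to complement and to NF-kB, picked after their values were seen and not tested as a group, were higher in senescent cells. Beside C3 (8.52), the classical complement proteases' genes C1S (64.1 ± 2.91 to 399.5 ± 4.77 CPM, log2 fold change 2.64 ± 0.0496) and C1R (1.76 ± 0.0465) and the C1 inhibitor gene SERPING1 (10.4 ± 0.619 to 150.4 ± 7.26 CPM, 3.86 ± 0.0652) rose in the edgeR test. So did genes that NF-kB is known to switch on and that restrain or carry its signal: TNFAIP3 (4.11 ± 0.0805), BIRC3 (3.69 ± 0.0911), NFKBIA (2.51 ± 0.0593), RELB (1.74 ± 0.0787) and NFKB2 (1.64 ± 0.0565), together with the leukocyte adhesion genes ICAM1, a member of the fixed cytokine list (24.7 ± 0.481 to 807 ± 3.24 CPM, 5.03 ± 0.0533) and VCAM1 (5.26 ± 0.0784), the prostaglandin synthase gene PTGS2 (3.77 ± 0.0941) and the IGFBP protease gene PAPPA (18.8 ± 0.767 to 470.3 ± 10.7 CPM, 4.64 ± 0.0565). Over 20% of the exon bases of ICAM1 and PAPPA lie in exons of a gene on the opposite strand, so their values are uncertain.

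Cell cycle regulators moved in opposite directions. CCND2, which encodes cyclin D2, rose from 0.445 ± 0.137 to 32.2 ± 0.640 CPM (6.18 ± 0.145) while its kinase partner's gene CDK4 fell (-1.05 ± 0.0475, uncertain because 43.2% of its exon bases lie in exons of an opposite-strand gene), as did E2F2 (-3.73 ± 0.269), E2F8 (-4.06 ± 0.208) and the RB-related gene RBL1 (-2.33 ± 0.0820). The differentiation inhibitors ID1, ID2 and ID3 fell (-3.33 ± 0.0857, -3.43 ± 0.0859 and -2.45 ± 0.0649) although BMP2, whose signal is known to induce them, rose (5.25). The histone variant genes H2AX (-2.96 ± 0.114) and H2AZ1 (-1.89 ± 0.0468) fell, unlike 8 of the 13 tested canonical histones. In the mitochondrial genome the counts of ribosomal RNAs did not follow those of the messages: RNR1 was at 289 ± 12.9 and 338 ± 10.3 CPM (0.23 ± 0.0460) and RNR2 at 2478 ± 42.6 and 2365 ± 1.02 CPM (-0.07 ± 0.0399, adjusted p = 0.133), against a median of -1.24 for the 13 protein-coding genes. How well these poly(A) libraries capture ribosomal RNAs was not measured, so the split may not reflect RNA levels. The rise of RNR1 has about the size of the shift of -0.23 that library totals put on the genes.

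TERT stood at 507 ± 23.3 and 215 ± 22.0 CPM, although fibroblasts are known for little or no telomerase, while its neighbours SLC6A18 and SLC6A19 on one side had 0 and 3 counts over all libraries, those on the other, CLPTM1L and SLC6A3, had 3965 (31.5 CPM) and 0, and DKC1, a telomerase partner, had 63.3 ± 1.20 and 25.2 ± 1.72 CPM. Reads shared with another annotated gene are argued against, since 0% of the 3944 words of 75 bases in the longest TERT transcript occur in transcripts of other genes. Epithelial, endothelial or leukocyte cells as a large part of the cultures are argued against as well: the highest of the median marker levels of these lists was 0.309 CPM in normal cells, with FLT1 (50.7 CPM) and TEK as the most abundant endothelial markers, and MUC1 (3.84 CPM) and CORO1A (2.87 CPM) as those of the other lists. A median cannot exclude a small share of such cells. An introduced TERT sequence, which the labels do not mention, may account for a rank of 222 among 14367 genes, but a single count per gene does not show which exons the reads cover. That explanation and expression from the cells' own gene cannot be told apart here.

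Transcripts named as antisense often changed with their sense partners. Among antisense genes with a mean log2 CPM of at least 1, the 193 pairs with overlapping exons had a Spearman rho of 0.739 between their log2 fold changes across pairs, which are not independent replicates, and differed by a median of 0.148, as in PAPPA-AS1 and PAPPA (4.55 and 4.64, with 100% of the antisense exon bases inside sense exons), while 18 pairs differed by over 1, such as SPAG5-AS1 and SPAG5 (-0.34 and -3.38) and OIP5-AS1 and OIP5 (-0.18 and -2.95). That reads of an abundant sense gene were also counted for its partner may play a part: the 72 overlapping pairs with a sense gene at least 8 times as abundant differed by 0.152, against 0.347 in the 25 with an antisense gene as abundant or more (permutation p = 0.0359, two-sided), but with no expression minimum, a setting added after the data were seen, the medians were 0.295 and 0.347 (p = 0.611), so this stays open. Counting without strand stays open as well, since overlapping pairs differed by 0.148 and the 13 pairs whose genes lie apart by 0.345 (permutation p = 0.161, and 0.357 with no minimum, over 318 and 22 pairs). Joint regulation cannot be told apart from these, with a rho of 0.516 in the 13 separate pairs and no counts per strand.

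Several broadly expressed genes had almost no reads. Among 189 genes for oxidative phosphorylation, ribosomal proteins, ribosome biogenesis and splicing, 5 lay under 5 CPM (RPS18, PRPF8, RRN3, RPS9 and U2AF1) and the next lowest, UTP4, at 11.6 CPM, and of 143 protein-coding genes between GABBR1 and KIFC1 on chromosome 6 (GRCh38, 29602238 to 33409896) 95.1% lay under 1 CPM, as did 92.3% of 39 between OSCAR and RDH13 on chromosome 19 and all 13 between ARHGAP27 and WNT3 on chromosome 17, against 38.7% elsewhere. For U2AF1, reads shared with an annotated copy may be the reason, as 98.4% of its words of 75 bases occur in other genes, chiefly U2AF1L5. U2AF1 had 20 and 18 counts in the normal libraries, and 215 and 15 in senescent replicates 1 and 2. The cause of that gap between replicates was not tested. For RPS9, RPS18, PRPF8 and RRN3 reads shared with another annotated gene are argued against as a common reason, since RPS9, RPS18 and PRPF8 had shares of 0.260%, 2.61% and 0% (RRN3 had 22.8%). The words were sought in annotated transcripts only, so copies on alternate sequences were not covered. RPS18 lies in the chromosome 6 stretch and RPS9 in that of chromosome 19, whereas PRPF8 and RRN3 lie outside these stretches. Loss of the whole chromosome 6 stretch from the cells is argued against by HLA-B at 264 CPM inside it. The hg38 build carries alternate sequences for such stretches, and reads left uncounted because they also match these are a candidate explanation that stays open, since neither those sequences nor alignments are used here.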
